A study of Homo sapiens with 8 samples.

How the data were processed

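Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA so that reads pile up where chromatin is accessible. The 8 libraries came from sorted human natural killer (NK) cells in 4 groups of 2 libraries each, with 50000 cells per library and 50 bp paired-end reads, per the labels' protocols. The labels give no donor, culture, day or batch, so it is not stated whether the libraries of a group came from separate donors or cultures, and p-values measure only the spread between these libraries.

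The authors deposited 1 table of whole-number read counts per region for all 8 libraries, with the width of each region in base pairs. Its 96411 regions are numbered without a gap, have a median width of 468 bp (157 to 5461 bp) and cover 54.6 Mb in all. The counts were not normalized: totals differed between libraries, from 12235636 to 22067020. The genome build was hg38, per the submitters' processing notes. The aligner, the peak caller, the treatment of duplicate reads, any correction for the transposase's cut position, and whether regions were called per library or on pooled libraries are not given in the sources used here. The table's regions carry numbers only, without positions or gene names, so regions are reported by number, width and counts. For the same reason the planned assignment of regions to genes, the gene list tests, the promoter shares, the sequence word tests and the removal of regions by chromosome were not done. Each table column was matched to a library by its name, and all 8 columns were used (0 were left unmatched). The 2 columns named only as double positive were given to the HNSCC-induced group because the other double positive group has columns named for TGF.

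Tests were run on the deposited counts with edgeR 4.0.16 in R 4.3.3. Low-count regions were removed with edgeR's default filter by group, which left 90523 regions. The 5888 regions removed held 0.175% of the counts. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust estimation and a mean per group was fitted to all 8 libraries, which leaves 4 residual degrees of freedom. A region was called when its Benjamini-Hochberg adjusted p was below 0.05 over all regions tested. Fold changes are log2 values from that model, and a standard error was derived from the fold change and its quasi-likelihood F value. Levels are edgeR's CPM (counts of a region relative to the total of its library) after TMM scaling, and correlations and principal components used log2 CPM with a prior count of 2. Counting alone does not account for the spread between libraries, though this was not split by signal and depth may still limit weak regions. On average over regions with at least 10 counts in the pair, libraries of a group differed by 6.66 to 9.64 times the variance that counting alone gives. They were therefore not 1 library deposited more than once, but this does not tell whether they were repeat libraries of 1 sample.

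The groups share the replicate numbers 1 and 2. Within each group the difference between replicate 2 and replicate 1 was computed per region, and these differences correlated between groups in all 6 pairs of groups (r = 0.349 to 0.505 across regions). Principal components 2 and 3 also separated the numbers in the same direction in all 4 groups. The numbers were therefore taken to pair the libraries, although the labels do not say what a number stands for. Each comparison has only 2 such pairs, and the counts from both models were seen together with this check, so the decision was not blind to them. The model fixed before the data were examined had no replicate term, so its counts are given first. Counts from the same model with the replicate number as a block, which leaves 3 residual degrees of freedom, are given beside them. The block reduced the common biological coefficient of variation from 27.1% to 14.4%.

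The model without the block was tested on simulated data for the comparison of TGF-β-induced double positive with control cells. In these data 200 regions were changed among 87858, all drawn from regions above a minimum mean count, and no replicate effect was simulated. It recovered 69 of 100 regions changed 4-fold and 14 of 100 changed 2-fold, none with the wrong sign. It made 16 false calls among 99, or 16.2%, which is above the nominal 5%. Recovery in weak regions and the share of false calls with the block were not measured. For comparisons that share the control libraries, unchanged groups were simulated in 10 draws from the blocked model, with its dispersions and replicate effect. All 8 libraries were drawn, controls included, and the model without the block was then fitted. The alternatives were library-size scaling, a cyclic loess offset (limma 3.58.1), DESeq2 1.42.0, looser and stricter filters, a fit of only the 2 groups compared, the replicate block, stricter thresholds, and leaving out each library. Thinning all libraries to 1 total, the block combined with other settings, and the overlaps of the 3 pairs of comparisons that share no library were added after seeing the data.

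The rule for named regions was the largest fold change in each direction among called regions with a mean log2 CPM of at least 2 and no overlap between the libraries of the 2 groups. It was fixed beforehand for 8 genes in each direction per comparison, beside fixed gene names and lists. Because the regions here have no gene names, it was applied to 1 higher and 1 lower region in each of 2 comparisons, and the 2 comparisons were chosen afterwards.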

Results

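ATAC-seq counts were compared across 4 groups of sorted human NK cells, which are lymphocytes that kill tumour and infected cells. The groups were control cells, cells called double negative and cells called double positive after induction by HNSCC (head and neck squamous cell carcinoma), and double positive cells induced by transforming growth factor-β (TGF-β), a cytokine. The labels do not name the pair of markers behind "double negative" and "double positive", and they give the cell type of all 8 libraries as ieILC1. Each group held 2 libraries. Counts in the 96411 regions totalled 16970073 and 16913357 in control replicates 1 and 2, and 12235636 and 19751912 in HNSCC double negative replicates 1 and 2. The totals were 22067020 and 18581050 in HNSCC double positive and 19887164 and 15109049 in TGF-β double positive replicates 1 and 2.

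The control and the HNSCC double negative libraries had the most similar accessibility profiles of any 2 groups, and TGF-β double positive libraries lay farthest from both. The mean Pearson correlation of log2 CPM across the 90523 regions tested was 0.937 between control and double negative libraries (4 pairs, 0.908 to 0.955). It was 0.905 between control and HNSCC double positive libraries and 0.867 between control and TGF-β double positive libraries. The 2 double positive groups correlated at 0.874. Libraries of 1 group correlated at 0.953 (control), 0.949 (HNSCC double negative), 0.954 (HNSCC double positive) and 0.930 (TGF-β double positive). Of the 24 ways to join each replicate 1 with a replicate 2, a set chosen after seeing the data, the real grouping had the highest mean correlation, 0.947 against 0.934 for the next (exact permutation test, one-sided p = 0.0417, the smallest possible). Among all 105 pairings, which ignore the numbers, the next reached 0.945. Control and double negative libraries of the same number correlated at 0.943 (replicate 1) and 0.955 (replicate 2), about as highly as libraries of 1 group. The first principal component held 41.2% of the variance and placed HNSCC double positive libraries, at 23.7 and 38.2, between the control and double negative libraries (-160 to -85.9) and the TGF-β libraries (195 and 197).

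**Figure D1:**
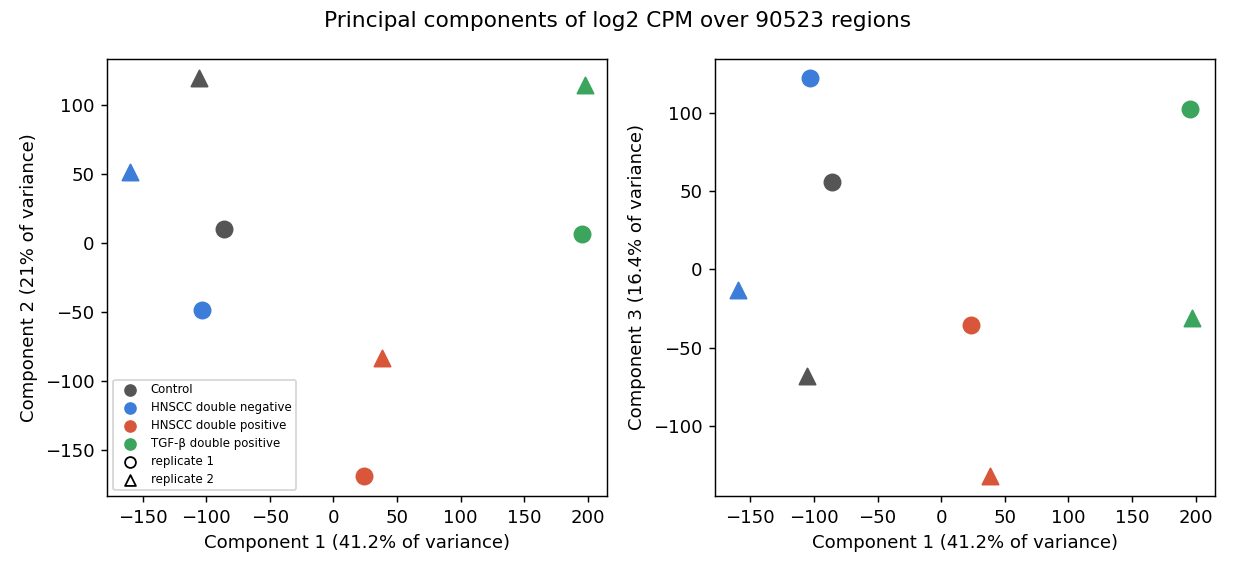
Principal components of log2 CPM over the tested regions, with component 1 (41.2% of variance) on the x axis and component 2 (21%) or 3 (16.4%) on the y axis. Each point is 1 library, coloured by group, with circles for replicate 1 and triangles for replicate 2. The groups separate along component 1 except control and HNSCC double negative, and triangles lie above circles on component 2 and below them on component 3 in each group.

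The first comparison was of HNSCC-induced double negative with control cells. Accessibility differed in few regions without the replicate block: 282 regions were higher and 213 lower in HNSCC double negative cells, 0.547% of those tested (edgeR quasi-likelihood test, adjusted p below 0.05). With the replicate block 4566 were higher and 4187 lower, and all 495 regions of the first set were among them with the same direction. The 282 regions called higher without the block had a median fold of 2.80 and were already accessible in control cells. Their median level was 8.92 CPM in control and 25.3 CPM in double negative cells. The regions that fell had a median fold of 3.55, from 10 CPM in control cells to 2.84 CPM. Regions that rose were wide, with a median of 721 bp against 493 bp for all regions tested. By mean log2 CPM over all 8 libraries, 177 of the 282 were among the 22631 regions with the highest signal. Of the 22631 with the lowest signal only 4 were called higher and 0 lower, so these medians describe mostly stronger regions. The calls made with the block were not broken down by level or width. The fold changes of replicate 1 and of replicate 2, which share no library, correlated at Pearson's r = 0.501 and Spearman's rho = 0.489 across regions, which are not independent replicates. The direction of the balance depended on scaling: with library-size scaling 39.6% of calls were higher, against 57.0% with TMM. Without the block, leaving out control replicate 1, control replicate 2 or double negative replicate 1 left 0 calls by edgeR (9975, 8044 and 9003 regions had an unadjusted p below 0.05), and leaving out double negative replicate 2 left 41. With the block 3735 to 4725 were left, and DESeq2 on all libraries without the block called 1769.

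The second comparison was of HNSCC-induced double positive with control cells. Of the regions tested, 4359 were higher and 2251 lower in HNSCC double positive cells, 7.30% in all (edgeR, adjusted p below 0.05), and with the replicate block 10907 and 8254. Regions that rose started from low accessibility, with a median of 1.01 CPM in control and 5.33 CPM in double positive cells, a median fold of 4.68, and 2583 rose more than 4-fold. Regions that fell went from a median of 9.11 CPM to 3.21 CPM, a median fold of 2.72. In this and the other comparisons, levels and folds of called regions come from the libraries that selected them. Low starts and large folds of regions that rose may thus come partly from the selection, and the level of all tested regions was not set beside them. Of the 22631 regions with the lowest signal, by mean log2 CPM over all 8 libraries, 4.54% rose and 0.451% fell. Of the 22631 with the highest signal 3.29% rose and 3.94% fell. That mean includes the libraries compared, so these classes do not give the level in control cells. The fold changes of the 2 replicates correlated at r = 0.715 and rho = 0.620 across regions. Without the block, leaving out 1 library at a time lowered the count to between 945 (without control replicate 2) and 2423 (without control replicate 1), and to 1370 and 1942 without HNSCC double positive replicates 1 and 2.

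A region of 700 bp, Interval_77480, had the largest rise that met the naming rule in HNSCC double positive cells, from 0.591 ± 0.312 CPM in control (SD, n = 2) to 29.5 ± 9.19 CPM (SD, n = 2), a log2 fold change of 5.62 (SE 0.576, edgeR adjusted p = 0.00214). Its level was 1.16 ± 0.591 CPM in HNSCC double negative and 20.9 ± 10.8 CPM in TGF-β double positive cells, and the difference between the 2 double positive groups did not pass the test without the block (edgeR adjusted p = 0.504) and did with it (adjusted p = 0.0253). The largest fall was in Interval_1185, a region of 386 bp, from 15.7 ± 3.75 to 1.27 ± 0.0392 CPM (SD, n = 2 each), a log2 fold change of -3.62 (SE 0.526, edgeR adjusted p = 0.00637). Without HNSCC double positive replicate 1 or 2 this region no longer passed, with edgeR adjusted p = 0.0635 and 0.0573 (5.03e-12 to 0.0635 over the alternatives, the lowest from DESeq2). The log2 fold changes in these 2 settings were -3.66 and -3.59.

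The third comparison was of TGF-β-induced double positive with control cells and gave the most calls of the 3 groups compared with control. In TGF-β double positive cells 9171 regions were higher and 4042 lower, 14.6% of those tested (edgeR, adjusted p below 0.05), and with the replicate block 17175 and 10652. The median fold of regions that rose was 4.84, from 0.869 CPM in control to 4.77 CPM, and 5528 rose more than 4-fold. Regions that fell did so from a median of 11.5 CPM to 4.32 CPM, a median fold of 2.47. Rises predominated in narrow regions and in those of low signal, by mean log2 CPM over all 8 libraries. Of the 22631 regions with the lowest signal 13.2% rose and 0.862% fell, against 5.89% and 8.59% of the 22631 with the highest signal. That mean includes the libraries compared, so a region high only in TGF-β cells tends to be classed as low. The classes therefore do not give the level in control cells. Of regions up to 300 bp wide 10.1% rose and 1.88% fell, and of those over 700 bp 6.58% rose and 7.01% fell. The TGF-β libraries also held less of their counts in the strongest regions, ranked by counts relative to library totals, summed over all 8 libraries. The top 5% of regions held 39.9 ± 2.0% of the counts (SD, n = 2) against a mean of 44.5% in the other 6 libraries. The lower 50% held 6.39 ± 0.111% (SD, n = 2) against 4.51%. HNSCC double positive libraries lay between the TGF-β and the remaining libraries, at 43.0 ± 0.127% and 5.24 ± 0.436% (SD, n = 2 each). For each, an exact permutation test over the 28 choices of 2 libraries gave two-sided p = 0.0357, the smallest possible, and 0.143 after adjustment over 8 tests. These choices ignored the replicate numbers, which were taken to pair the libraries, so the p-value does not respect that pairing. The ranking draws mostly on the other groups, so it does not measure how evenly counts were spread within a library. The fold changes of the 2 replicates correlated at r = 0.762 and rho = 0.694 across regions. Without the block, leaving out control replicate 2 left 4261 calls and control replicate 1 left 5804, and without TGF-β replicates 1 and 2 there were 9264 and 9042.

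The largest rise that met the naming rule in TGF-β double positive cells was in Interval_73105, a region of 740 bp, from 0.916 ± 0.510 CPM in control to 68.3 ± 12.3 CPM (SD, n = 2 each), a log2 fold change of 6.20 (SE 0.425, edgeR adjusted p = 0.000122). HNSCC double positive cells had 6.47 ± 1.17 CPM there (SD, n = 2), which was above control (log2 fold change 2.80, edgeR adjusted p = 0.00576) and below TGF-β double positive cells (log2 fold change of TGF-β over HNSCC 3.40, adjusted p = 0.0011). The largest fall was in Interval_85564, a region of 909 bp, from 16.5 ± 5.38 to 0.730 ± 0.0445 CPM (SD, n = 2 each), a log2 fold change of -4.48 (SE 0.335, edgeR adjusted p = 0.000124). This region was higher than control in HNSCC double negative cells, at 60.8 ± 2.0 CPM (edgeR adjusted p = 0.0316, and 3.38e-06 with the block), and lower in HNSCC double positive cells, at 1.84 ± 0.626 CPM (adjusted p = 0.00122). The call in double negative cells was lost, with all others of that comparison, without the block when control replicate 1, control replicate 2 or double negative replicate 1 was left out, and in an edgeR fit of those 2 groups alone.

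**Figure D2:**
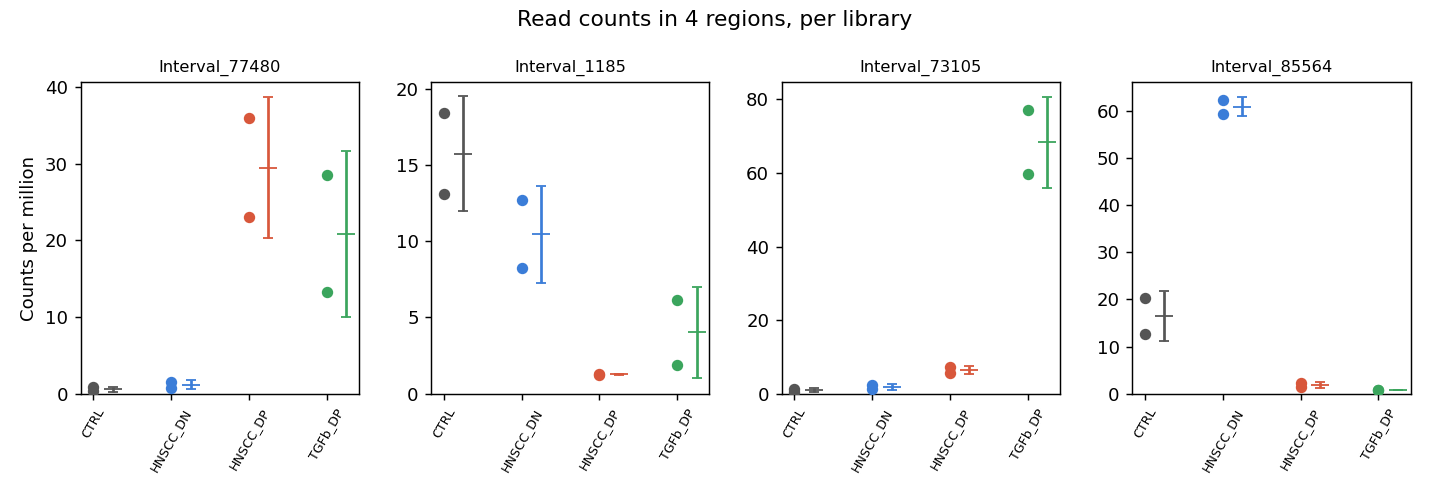
CPM in 4 regions, with the groups CTRL (control), HNSCC_DN and HNSCC_DP (HNSCC-induced double negative and double positive) and TGFb_DP (TGF-β-induced double positive) on the x axis. Each dot is a library, and bars beside the dots are the mean ± SD of 2 libraries. Interval_77480 is high in both double positive groups, Interval_73105 is highest in TGF-β double positive cells, and Interval_85564 is highest in HNSCC double negative cells at 60.8 CPM.

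The fourth comparison set the 2 HNSCC-induced populations against each other. Relative to double negative cells, 4812 regions were higher and 3788 lower in double positive cells, 9.5% of those tested (edgeR, adjusted p below 0.05), and with the replicate block 12285 and 10339. Regions that rose had a median fold of 4.04, from 1.20 to 5.23 CPM, and regions that fell a median fold of 2.66, from 11.5 to 3.98 CPM. Regions that fell were wider, with a median of 681 bp against 488 bp for those that rose. The share of calls that were higher was 56.0% with TMM, 50.6% with DESeq2 and 67.4% with library-size scaling, which moved the median log2 fold change of all regions from 0.05 to 0.18. Fold changes of the 2 replicates correlated at r = 0.657 and rho = 0.599 across regions. Without the block, leaving out 1 library lowered the count to 3490 and 2125 (double negative replicates 1 and 2) and to 2152 and 2320 (double positive replicates 1 and 2).

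The fifth comparison was between the double positive groups. In TGF-β double positive cells 6281 regions were higher and 3963 lower than in HNSCC double positive cells, 11.3% of those tested (edgeR, adjusted p below 0.05), and with the replicate block 14974 and 10733. The regions that were higher had a median fold of 3.75, from 1.52 CPM in HNSCC to 6.46 CPM in TGF-β cells, and those that were lower a median fold of 3.12, from 8.01 to 2.37 CPM. The fold changes of the 2 replicates correlated at r = 0.725 and rho = 0.668 across regions. Without the block, leaving out HNSCC double positive replicates 1 and 2 left 2071 and 3055 calls, and leaving out TGF-β replicates 1 and 2 left 7170 and 6025.

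**Figure D3:**
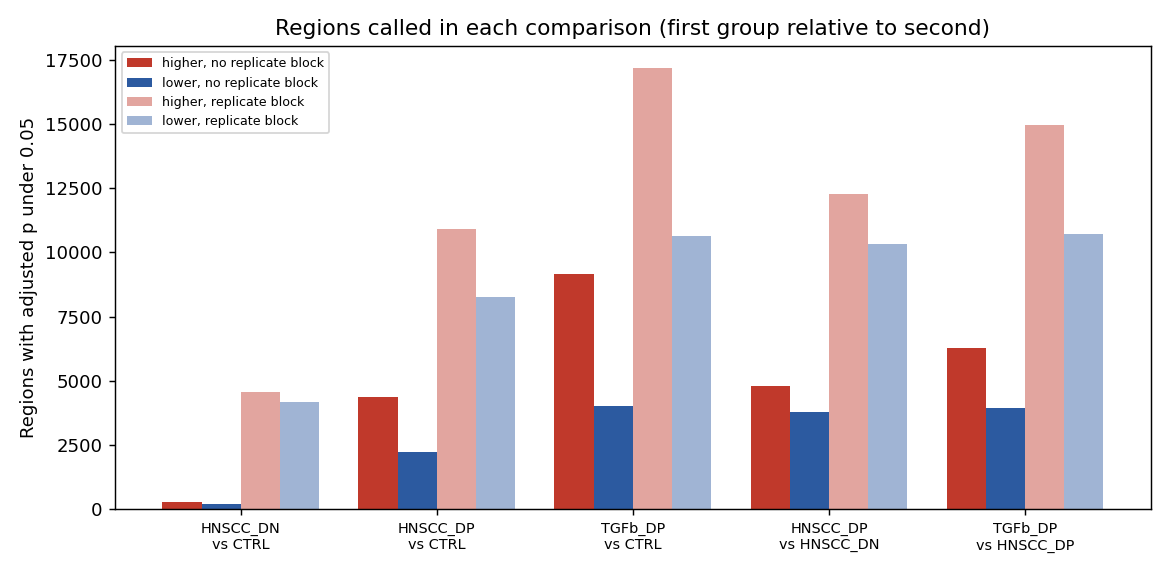
Number of regions with an edgeR adjusted p below 0.05 in each comparison, higher (red) or lower (blue) in the first group named, with dark bars for the model without and pale bars for the model with the replicate block. Of the 5 comparisons plotted, HNSCC_DN against CTRL has the fewest calls in both models (495 and 8753) and TGFb_DP against CTRL the most (13213 and 27827).

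The changes against control overlapped between the double positive groups. Of the regions called against control, 1910 were higher and 987 lower in both the HNSCC and the TGF-β double positive cells, where independent lists of these sizes would share 442 and 101, and 68 went opposite ways against 423. With the block 5604 were higher in both (independent lists, 2070), 3684 lower in both (971) and 687 opposite (2850). Among the 1910 regions that rose in both, the direct comparison of the 2 groups called 275 higher and 135 lower in TGF-β cells and did not call 1500. A further 7223 regions were called higher against control in TGF-β cells and were not called in HNSCC double positive cells, and for 3797 of these the direct comparison was called higher in TGF-β cells. In the other direction, 2419 regions were called higher in HNSCC double positive cells and not called in TGF-β cells, with 1322 called lower in TGF-β cells directly. Both sets were picked on the same double positive libraries that the direct comparison uses, so these direct calls are no separate evidence. The 2 sets of fold changes correlated at r = 0.551 across regions, where simulated unchanged groups that shared simulated control libraries gave 0.524. No shared call arose in 10 draws, but no region was changed there. The simulation thus cannot tell how far shared controls raise the overlap of real calls. Their covariance was 0.609 against 0.0964 simulated, a difference of 0.513. With fold changes of log2 CPM taken from different replicate numbers, so that each comparison had its own control library, r was 0.371 and 0.410 in the 2 ways to split, against 0.521 on that scale with shared controls, and the mean covariance was 0.381 against 0.442. This split was added after seeing the data and was not made for the calls, so part of the excess over independent lists may come from the shared controls. Independent lists, here and below, also assume that every region is equally likely to be called. Of the 22631 regions with the lowest signal 0.451% fell in HNSCC and 0.862% in TGF-β double positive cells. Of the 22631 with the highest signal 3.94% and 8.59% fell. Part of the excess may come from this too.

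HNSCC double negative cells, with their shorter list of calls, shared fewer regions with the double positive groups. With HNSCC double positive cells they shared 126 regions higher and 32 lower than control (independent lists, 13.6 and 5.30), 27 went opposite ways (17.3), and the covariance of fold changes exceeded the simulated one by 0.178. With the block these counts were 1919 higher (550), 1196 lower (382) and 754 opposite (921), so that opposite calls went from above to below the number for independent lists. With TGF-β double positive cells they shared 116 higher and 26 lower (independent lists, 28.6 and 9.51), 77 regions went opposite ways (34.2), and the covariance exceeded the simulated one by 0.077. With the block they were 1622 higher (866), 784 lower (493) and 1668 opposite (1330). The correlations, 0.388 and 0.203, were below the 0.503 and 0.495 that unchanged groups gave. With the controls split, r was 0.243 and 0.166 with HNSCC double positive cells, and 0.144 and -0.00825 with TGF-β double positive cells.

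The 4 groups can be set against each other in 3 pairs of comparisons that share no library, and all 3 were examined after seeing the data. The pair with the highest correlation was HNSCC double positive against double negative cells with TGF-β double positive against control cells. Regions called higher in both numbered 1633 and lower in both 1264, where independent lists would share 488 and 169, and 222 regions were called in opposite directions against 599. The numbers for independent lists again take every region as equally likely to be called, although call rates differed with signal level. With the block the numbers were 5133 (2330), 4065 (1220) and 1290 (3410), with those for independent lists in parentheses. Of the regions called higher in TGF-β double positive cells, 75.4% had a positive fold change between HNSCC double positive and double negative cells (median log2 fold change 0.64), and of those called lower 82.3% had a negative one (median -0.58). Fold changes correlated at r = 0.395 and rho = 0.408 across regions, which are not independent replicates. Both comparisons also had a trend with signal level. In the 22631 regions with the lowest signal the median log2 fold changes were 0.398 (HNSCC) and 0.636 (TGF-β). In the 22631 with the highest signal they were -0.171 and -0.231. The overlap was not examined with the loess offset, so part of these shares and of this correlation may come from such a trend. The pair of HNSCC double positive against control with TGF-β double positive against HNSCC double negative cells gave r = 0.283 and rho = 0.257. The second of these, not among the 5 comparisons above, had 21584 calls, and 37366 with the block, more than any of the 5. The pair had 1512 regions higher in both (627), 987 lower in both (213) and 437 opposite (736). With the block these were 4561 (2580), 3312 (1450) and 2468 (3870). In the pair of HNSCC double negative against control with TGF-β against HNSCC double positive cells the correlation was r = -0.135 and rho = -0.171. This is not a separate observation, since its covariance (-0.101) equals that of the preceding pair (0.335) minus that of the first (0.436) by construction. There 132 regions went opposite ways (independent lists, 27.1), 55 were higher in both (19.6) and 13 lower in both (9.32). With the block 2841 went opposite ways (1230), 853 were higher in both (755) and 462 lower in both (496), so that shared lower calls went from above to below the number for independent lists.

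**Figure D4:**
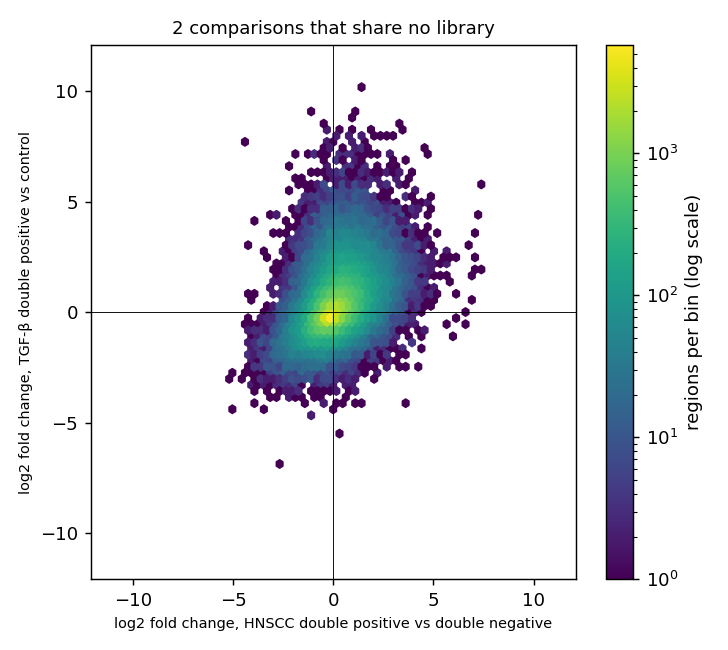
Log2 fold change of HNSCC double positive against double negative cells (x axis) and of TGF-β double positive against control cells (y axis), the pair with the highest correlation of the 3 that share no library, for the 90523 tested regions. Colour gives the number of regions per hexagonal bin on a log scale, and the cloud tilts upward (r = 0.395).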

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

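The replicate block was among the alternatives fixed beforehand, but its use as a test of the low count in double negative cells was chosen only after the result was seen, as were the loess offset and thinning combined with the block. Groups of 2 libraries are too small to look for outlying samples.

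Regions called in opposite directions against control in the double positive groups were singled out because their effects differed between the groups. There were 68, against 423 for independent lists, and 687 with the replicate block, against 2850. All 68 were also called in the direct comparison (edgeR, adjusted p below 0.05), but opposite effects against a shared control add up there, so this is no further evidence. HNSCC double positive cells had the higher level in 30 and TGF-β double positive cells in 38.

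The number of calls against control rose from HNSCC double negative (495) to HNSCC double positive (6610) and TGF-β double positive cells (13213), with 69.4% of the last higher than control. The TGF-β libraries also held more of their counts in regions that were weak over all libraries, and HNSCC double positive libraries lay between them and the rest. Counts spread more evenly within the TGF-β libraries, which was not measured, could raise weak regions and lower strong ones without any change at single sites. With the replicate block alone there were 27827 calls in TGF-β and 19161 in HNSCC double positive cells. Of these TGF-β calls 61.7% were higher. Adding a loess offset that removes trends with signal level left 24310 and 18893 calls, a ratio of 1.29, with 61.2% of the TGF-β calls higher. Such a trend is therefore not the whole cause of the larger number of calls or of the excess of higher ones. Thinning every library to the smallest total, with the block, left a ratio of 1.49. On average depth did not favour TGF-β cells to begin with: the mean total was 17500000 in TGF-β and 20320000 in HNSCC double positive libraries. Thinning took more from the latter, so this ratio could not test depth. Background that differs between sites of equal signal, GC content and a biological difference between the inducing conditions were not tested and remain open.

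HNSCC double negative cells had the fewest calls against control, and the difference between replicate numbers may have hidden much of their change, since the block raised the count to 8753. It did not raise it to the level of HNSCC double positive cells: the ratio of the 2 counts was 0.457 with the block, and 0.459 with the block after thinning, which also argues against the low depth of double negative replicate 1. A smaller change from control than in double positive cells stays as a hypothesis. It was found on these same libraries, and what the replicate numbers stand for is not stated.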

How the results depend on the processing

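The combination of the replicate block with other settings and the thinning of libraries were chosen after seeing the data. Of the counts of called regions and overlaps, 33 stayed within 1.5 times their value and 31 did not, leave-one-out settings aside. Those outside follow, always in the order HNSCC double negative against control, HNSCC double positive against control, TGF-β double positive against control, HNSCC double positive against double negative, and TGF-β against HNSCC double positive. An adjusted p below 0.01 gave 13, 1684, 4818, 2367 and 2954 calls, and a test against a minimum fold of 1.5 gave 23, 2907, 6895, 3483 and 4479. The replicate block gave 8753, 19161, 27827, 22624 and 25707. The replicate block with a loess offset gave 8747, 18893, 24310, 21250 and 26353, so that the last, not TGF-β against control, was then the highest of these 5. The replicate block after thinning gave 7801, 17012, 25275, 20381 and 22724. For HNSCC double negative against control, DESeq2 called 1769 regions (9162 with an unadjusted p below 0.05) and an edgeR fit of those 2 groups alone called 0 (11779 with an unadjusted p below 0.05, edgeR). The same-direction overlap of both double positive groups against control (2897) was 9288 with the block and 692 at an adjusted p below 0.01, and that of HNSCC double positive against double negative with TGF-β against control (also 2897) was 9198 and 673. Leaving out 1 library, with the lone library of its group assumed to vary like the other groups, gave 0 to 41, 945 to 2423, 4261 to 9264, 2125 to 3490 and 2071 to 7170 calls without the block, and 3735 to 4725, 9477 to 11552, 15986 to 22656, 11042 to 17285 and 12063 to 21049 with it. Between these ends lay, with the block and more than 1.5 times from the count of all libraries without it, 3875 and 4165 for the first comparison without control replicate 2 and double negative replicate 1, 11199 and 10204 for the next without control replicates 1 and 2, and 21661 for TGF-β against control without TGF-β replicate 2. Also that far off were 15411 for HNSCC double positive against double negative without double positive replicate 1, and 17434 and 20272 for TGF-β against HNSCC double positive without HNSCC replicate 2 and TGF-β replicate 1. Fewer libraries may lower these counts, but need not. A fit of only the 2 groups compared called 8078 regions, against 6610, for HNSCC double positive against control. It called 9188, against 8600, for HNSCC double positive against double negative. For the other comparisons it called fewer, with 0, 9721 and 6966 in the order above. The cause of the shifts was not tested. In the comparison each was chosen in, the 4 named regions kept their direction under the settings run for them, and Interval_1185 lost its call without either HNSCC double positive library. The call of Interval_85564 in double negative cells (edgeR adjusted p = 0.0316) was lost wherever that comparison had 0 calls, and at an adjusted p below 0.01. It held with the replicate block (edgeR adjusted p = 3.38e-06) and was not examined in the other settings. Library-size scaling shifted the median log2 fold change of all regions to 0.18 for HNSCC double positive against double negative and 0.13 for TGF-β against control. Not run, for lack of positions and sequence, were the GC-content offset and the alternatives for gene lists, promoter shares and sequence words. Thinning alone lowered the counts to 474, 5843, 11885, 7664 and 9127, none beyond 1.5 times. It tests only a loss of depth, so depth is not excluded as a limit beside the number of libraries.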

Other observations

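The tests on neighbouring regions were chosen only after their correlation was seen, and those of signal level, width and distance after their own values were seen as well.

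Regions with consecutive numbers tended to change together. In TGF-β double positive against control cells, fold changes of neighbours by number correlated at r = 0.278 over 85300 pairs, against at most 0.0090 in 100 shuffles, and HNSCC double positive against double negative cells gave 0.372. A region next to one called higher was itself called higher in 26.4% of cases against 10.1% of all regions, and next to one called lower in 5.13%. The pattern was not particular to the groups: the difference between replicates 2 and 1, averaged over the 4 groups, correlated between neighbours at 0.277 (0.133 at 5 apart and 0.0267 at 50 apart). The disagreement between the 2 replicates' fold changes also did, at 0.126 for TGF-β double positive, 0.118 for HNSCC double positive and 0.0807 for HNSCC double negative against control. Noise within single libraries may contribute, and is argued against as the whole cause by the correlation of a region's fold change in one replicate with its neighbour's in the other, 0.238, and a trend with signal level or width by the correlation left after both were regressed out, 0.277. A candidate explanation is that the numbers follow position on the chromosomes and that nearby regions vary together, between replicate numbers as well as between groups: at 50 numbers apart the correlation fell to 0.0188, which is 0.0676 of its value between neighbours. Positions were not used here, so neither distances nor shared GC content could be examined, and whether the variation is technical or biological remains open.

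Of the 12 regions with the highest counts, 6 lay within a run of 7 consecutive numbers. That run held 0.691% and 1.26% of all counts in the TGF-β double positive libraries and 1.33% to 2.01% in the other 6 libraries.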
